A study of Mus musculus with 29 samples.

How the data were processed

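The series listed 29 samples. Of these, 13 from chromatin accessibility and bulk RNA sequencing came without files and were not analysed here, and 16 single-cell RNA libraries came with count matrices. The deposited matrices hold UMI counts per gene and barcode. Per the submitters' processing notes they were made with Cell Ranger 6.1.1 against mm10. Per the file headers the software version was 3.0.2 for 12 libraries with 31053 genes and 6.1.0 for 4 in vivo libraries with 32285 genes, which disagrees with those notes. Groups were taken from the labels, 2 libraries each. The labels contradict each other on the sort of the cells, and the deleted part of Txnip is not given in the sources used here.

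Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept, which was 17.2 to 93.1% of barcodes per library. Scrublet marked 0 to 0.68% of cells per library, too few for the loading, so that it has not worked here, and its marks were used only in an alternative. Cells were clustered within each experiment in scanpy 1.11.5 (10000 counts per cell, log scale, 2000 variable genes, 30 principal components, 15 neighbours, Leiden clustering at resolution 0.8). A cluster was called another cell type when its 10 leading genes held at least 3 markers from the lists other than the T cell list, counted together. It was called cycling when they held at least 2 cell cycle genes. By this rule 1 cluster of effector cells of the Txnip experiment with a median of 960.0 UMIs counted as cycling, so that leaving cycling clusters out also removes barcodes with little RNA. Clusters of other types were left out of the sums. Shares of cells have exact Clopper-Pearson intervals.

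UMI counts of the kept cells were summed per library and tested in edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, quasi-likelihood test), with Benjamini-Hochberg adjusted p under 0.05. The first transfer and in vivo experiments were fitted alone and the 8 libraries of the Txnip experiment in 1 fit with 4 groups. Residual degrees of freedom were 2, 4 and 2 for the first transfer, Txnip and in vivo experiments, and prior degrees of freedom 8.57, 12.7 and 5.18. Recovery was tested on simulated data drawn from the libraries, with 200 changed genes, 100 at each fold. These went up and down in equal numbers and were drawn only from genes above a floor of mean CPM. In the data 68.7% of genes were called in the first transfer and 64.5% in the in vivo comparison. Recovery and false calls therefore do not carry over to genes with low counts or to comparisons over time.

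The 7 comparisons, their tests, 22 gene lists, 14 lists of cell type markers, the rule for naming genes and the alternatives were fixed before the data were examined, except those said to be added later. Lists were tested with camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation and fry as alternatives. List medians were the same with genes absent from a group set at their bound of 3 counts. A gene was named when its adjusted p was under 0.05, its mean reached 20.0 CPM in 1 of the groups and all libraries of 1 group lay on the same side of the other's. The 10 largest changes in each direction were eligible, without gene models, ribosomal, mitochondrial and sex-linked genes and receptor or immunoglobulin segments. For the interaction the rule on sides was not used. Up to 4 genes of each list with the smallest p, and Txnip, Arrdc4, Blvrb, Nfe2l2, Hmox1, Bcl2 and Bcl2l11, were eligible in every comparison. Genes within 10 Mb of Txnip were taken from the RefSeq table of the build, which matched 93.6% of the tested genes.

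Alternatives were DESeq2 1.42.0 (size factors, and its Wald test without the filter on low counts but with its own independent filtering), no filter on low counts, all barcodes, other cell types kept, Scrublet marks left out, cycling clusters left out, equal depth, a change of at least 1.2-fold, other samples in the fit, the replicate number as a block and each library left out. Added after the data were seen were at least 1000 genes per cell, at most 5 or 20% mitochondrial UMIs, cells with under 0.5% mitochondrial UMIs and at least 3000 UMIs left out, no scaling, and barcodes shared by the day 11 libraries kept only where they held more UMIs, or left out of both. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and matplotlib 3.10.9.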

Results

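The series concerned thioredoxin-interacting protein, encoded by Txnip, in T helper 2 (Th2) cells of the mouse and in the formation of memory T cells. It listed 29 samples, of which 16 were single-cell RNA libraries (10x Genomics 3' chemistry) with count matrices. They formed 8 groups of 2. In the first transfer experiment, DO11.10 cells with a transgenic T cell receptor for ovalbumin were made into Th2 cells in culture. They were measured either as effector cells at 0 h or from the spleen 48 h after intravenous transfer into BALB/c mice. The Txnip experiment had the same 2 times in libraries labelled Txnip WT and Txnip KO (knockout). In the in vivo experiment, naive CD4 T cells were transferred, ovalbumin in alum was given on days 1 and 6, and spleen cells were measured on day 7 and day 11. Each library held 5315 to 12233 barcodes and 34.7e6 to 102.5e6 UMIs (unique molecular identifiers). Of these, 20.0e6 to 100.4e6 per library entered the sums that were tested. The labels do not say that replicates came from separate mice or cultures, so p-values measure only the spread between these libraries, which may be technical. Values after ± are approximate standard errors of log2 fold changes, with n = 2 libraries per group. They were computed as the size of the change divided by the square root of the edgeR F statistic. For genes almost absent from 1 group they can be too small. In the part on results flagged for a closer look they are instead standard errors of a median over genes, which do not measure the spread between libraries. An adjusted p is the edgeR quasi-likelihood test with Benjamini-Hochberg correction, or the camera gene list test where a list is named.

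Txnip (chromosome 3, 96557957 to 96561857, mm10) was measured in every library to check the genotype labels, and it was not lower in the libraries labelled KO. Among effector cells its level was 32.5 and 27.6 CPM (counts per 1e6) in the WT-labelled libraries and 33.4 and 29.8 CPM in the KO-labelled ones, a log2 fold change of 0.07 ± 0.09 (adjusted p = 0.702). At 48 h it was 370.5 and 343.7 CPM in the WT-labelled and 686.6 and 672.1 CPM in the KO-labelled libraries, higher by 0.93 ± 0.07 (adjusted p = 1.2e-06). Which part of the gene was deleted is not given in the sources used here, and a 3' tag that lies outside the deleted part would check nothing. Groups are therefore named by their labels, and each direction between genotypes below rests on those labels alone. In the first transfer and Txnip experiments, time is not separated from the move from culture into mice. Txnip was higher at the later time in every experiment. It rose from 46.8 and 36.6 CPM in effector cells to 201.3 and 246.4 CPM at 48 h in the first transfer experiment (2.42 ± 0.13, adjusted p = 4.4e-08). Its rise was 3.57 ± 0.09 in the WT-labelled and 4.42 ± 0.09 in the KO-labelled libraries. In vivo it went from 26.8 and 26.1 CPM on day 7 to 123.1 and 108.6 CPM on day 11 (2.13 ± 0.09, adjusted p = 1.1e-05).

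**Figure D1:**
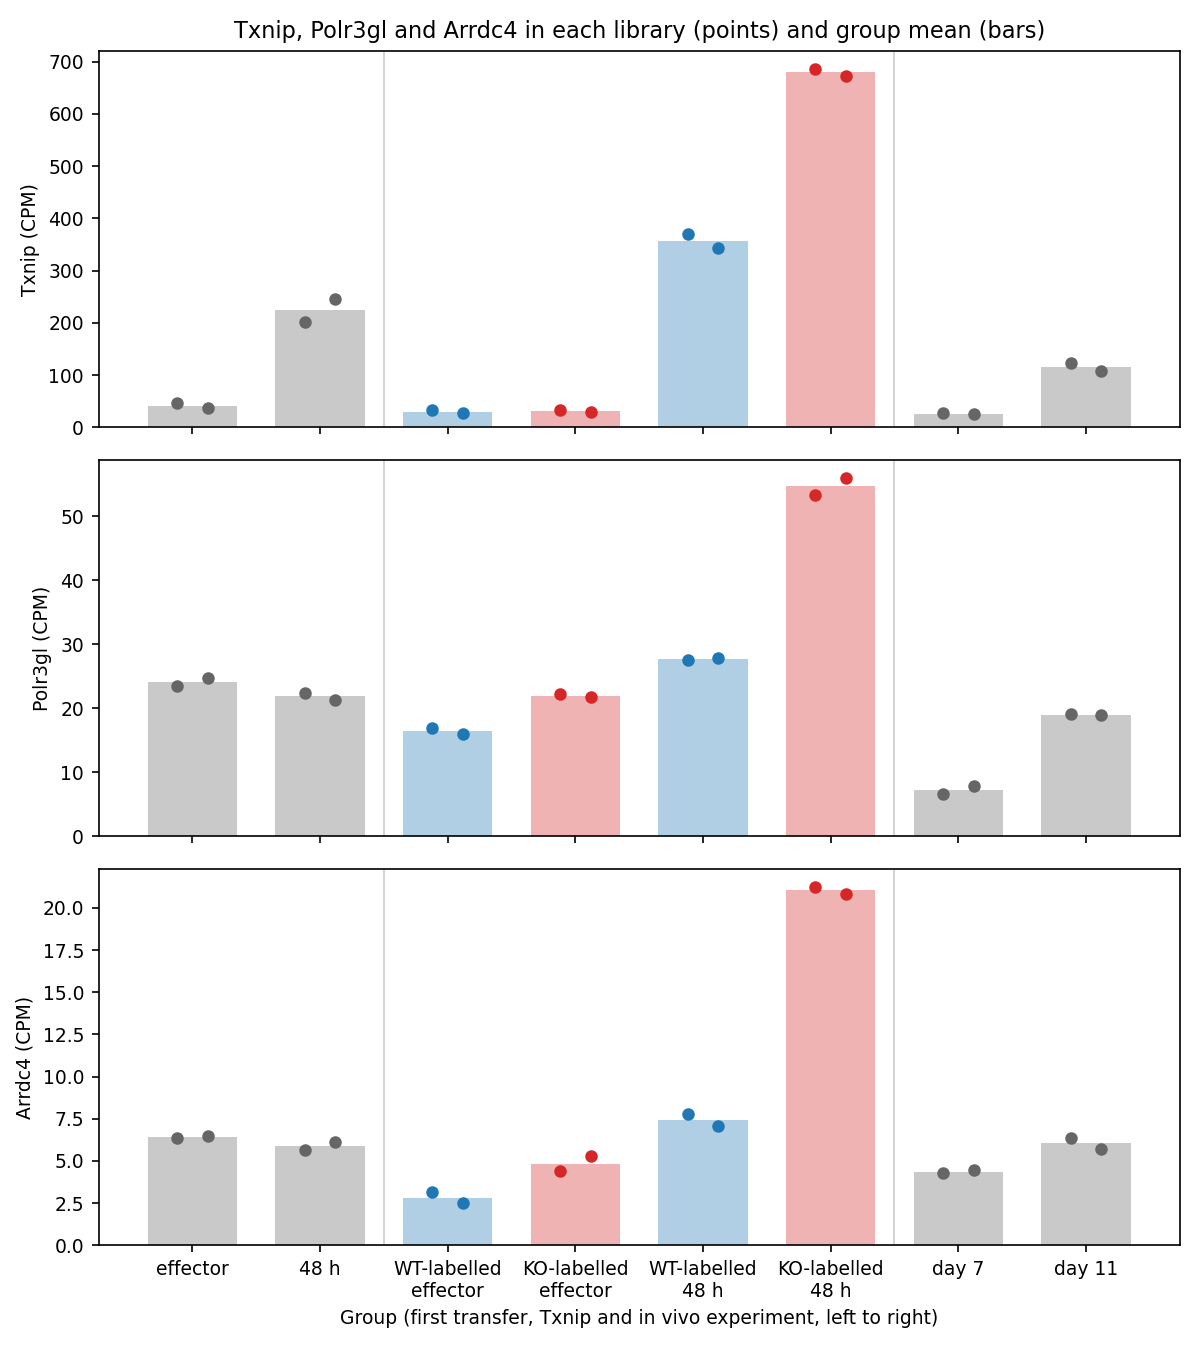
CPM of Txnip, Polr3gl and Arrdc4 (vertical axes) in the 8 groups of libraries (horizontal axis), with points for libraries and bars for group means. The KO-labelled 48 h libraries held 686.6 and 672.1 CPM of Txnip, above the 370.5 and 343.7 CPM of the WT-labelled ones.

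To learn what changes in Th2 cells during the first 48 h after transfer, the transferred cells of the first experiment were compared with effector cells. The cytokine gene Il13 fell by 9.90 ± 0.21 on the log2 scale, Il24 by 11.90 ± 0.16 and Il10 by 8.26 ± 0.12. Pth, a hormone gene with 195 CPM in effector cells, had no counts at 48 h. It was at least 7670-fold lower, against a floor of 3 counts over the group. Also lower were Tnfrsf9 (4-1BB, -7.63 ± 0.17), Ctla4 (-5.58 ± 0.09), Il2ra (the high-affinity interleukin 2 receptor chain, -4.71 ± 0.13) and Tnfrsf4 (OX40, -4.34 ± 0.10). Irf4, a transcription factor induced by receptor signalling, fell as well (-3.26 ± 0.09). Tcf7, a transcription factor of naive and memory T cells, rose by 5.14 ± 0.10, Cd27 by 2.94 ± 0.09 and S1pr1, the receptor that lets lymphocytes leave lymphoid organs, by 2.62 ± 0.11. Deptor, an inhibitor of mTOR, rose by 7.36 ± 0.15, Ms4a4b by 6.68 ± 0.17 and the chemokine receptor Ccr2 by 5.02 ± 0.16. Of 12588 genes tested, 4426 were higher and 4227 lower at 48 h, 3164 of them by at least 1 on the log2 scale. Cell quality moved with time, since 38.25 and 29.14% of barcodes were kept from effector and 54.62 and 75.89% from 48 h libraries, so that time and RNA quality are not separated here. Effector cells came from culture and 48 h cells from spleen, and time is not separated from that move either. The count of 8653 genes was 8384 with at most 5% mitochondrial UMIs.

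Among the lists fixed before the data were examined, 19 of 21 glycolysis genes fell and 1 rose (adjusted p = 1.6e-20, and adjusted p = 0.111 with an estimated correlation). Slc16a3, a lactate exporter, was at -5.28 ± 0.11 and Tpi1 at -3.17 ± 0.09. In cholesterol synthesis, 21 of 23 genes fell and none rose (adjusted p = 9.0e-20, and adjusted p = 0.111 with an estimated correlation). Fdps was at -3.01 ± 0.10 and Insig1 at -2.83 ± 0.08. The Th2 effector list had 15 lower and 5 higher of 23 genes (adjusted p = 2.6e-12, and adjusted p = 0.111 with an estimated correlation). Regulatory T cell genes had 7 lower and 1 higher of 10 (adjusted p = 3.2e-10, and adjusted p = 0.153 with an estimated correlation). A small cluster with the regulatory T cell genes Ikzf2 and Foxp3 among its leading genes nonetheless occurred only at 48 h (72 and 67 cells). Activation genes had 15 lower and 11 higher of 27 (adjusted p = 5.3e-07, and adjusted p = 0.151 with an estimated correlation). The unfolded protein response had 20 lower and 4 higher of 25 (adjusted p = 1.7e-06, and adjusted p = 0.254 with an estimated correlation), with Xbp1 at -2.62 ± 0.10 and Asns at -3.01 ± 0.11. In the cell cycle lists, 43 of 52 G2/M genes were lower and 1 higher (adjusted p = 4.2e-05), and 35 of 42 S phase genes were lower and 2 higher (adjusted p = 3.1e-04), each with adjusted p = 0.64 with an estimated correlation. NRF2 targets had 18 lower and 5 higher of 30 genes (adjusted p = 0.0221, and adjusted p = 0.255 with an estimated correlation). MYC and ribosome biogenesis genes had 17 lower and 2 higher of 29 (adjusted p = 0.0302, and adjusted p = 0.647 with an estimated correlation). Interferon-induced genes had 27 higher and 3 lower of 33 (adjusted p = 2.7e-07, and adjusted p = 0.383 with an estimated correlation). Ifi203 was at 3.97 ± 0.11 and Slfn5 at 3.44 ± 0.14, while Ly6a fell by 5.07 ± 0.13. Naive, memory and homing genes had 15 higher and 3 lower of 22 (adjusted p = 9.2e-07, and adjusted p = 0.204 with an estimated correlation), with Ccr7 lower (-1.82 ± 0.08). Handling stress genes had 13 higher and 5 lower of 22 (adjusted p = 0.0014, and adjusted p = 0.204 with an estimated correlation). Fosb was at 8.26 ± 0.32 and Fos at 2.86 ± 0.12.

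The remaining lists were not past the camera threshold. Nuclear genes of oxidative phosphorylation had 37 lower and 1 higher of 70, antioxidant and thiol genes 19 lower and 10 higher of 32, proapoptotic genes 8 lower and 6 higher of 23, and antiapoptotic genes 5 lower and 6 higher of 12. Ribosomal proteins had 8 higher and 1 lower of 56, mitochondrially encoded genes 6 higher and 1 lower of 13, and the MondoA and arrestin-domain genes 4 higher and 1 lower of 7. Follicular helper genes had 4 higher and 4 lower of 9, and Th1 genes 6 higher and 3 lower of 10. Adjusted over the list alone, counts differed only for handling stress (14 higher), interferon (28 higher), NRF2 targets (6 higher, 19 lower), oxidative phosphorylation (36 lower) and ribosomal proteins (5 higher, 0 lower). Median, mean and test differed in sign for the antiapoptotic (median 0.21, mean -0.23), follicular helper (median -0.14, test up) and Th1 lists (median 0.96, mean -0.06). Among genes fixed for every comparison, Nfe2l2, the gene of NRF2, rose by 1.27 ± 0.09, while Hmox1 (-2.67 ± 0.10), Bcl2 (-1.83 ± 0.08) and Blvrb (-0.45 ± 0.08) fell. Arrdc4 (-0.12 ± 0.12, adjusted p = 0.376) and Bcl2l11 (0.12 ± 0.11, adjusted p = 0.358) were not past the threshold. Plasma cell markers were lower (4 of 4 genes, adjusted p = 3.8e-04, and adjusted p = 0.355 with an estimated correlation). B cell markers had 5 lower and 2 higher of 8 (adjusted p = 0.00549, and adjusted p = 0.355 with an estimated correlation). On data simulated from these libraries with 12398 genes tested, all 100 genes changed 2-fold and 95% of those changed 1.5-fold were recovered, and 9.3% of calls were false. Only 200 genes changed in that simulation, far fewer than were called in the data.

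The same time comparison was made within each genotype label of the Txnip experiment. Il24 was at -11.52 ± 0.17 in the WT-labelled and at -10.79 ± 0.17 in the KO-labelled libraries. In the same order, Il13 was at -6.73 ± 0.16 and -6.71 ± 0.16, Il10 at -6.07 ± 0.09 and -6.45 ± 0.10, Il2ra at -4.68 ± 0.08 and -4.45 ± 0.08 and Tnfrsf9 at -5.94 ± 0.13 and -6.23 ± 0.14. Tcf7 rose by 5.41 ± 0.10 and 5.71 ± 0.12, and Il7r, the interleukin 7 receptor, by 3.41 ± 0.07 and 3.39 ± 0.07. Deptor rose by 8.43 ± 0.17 and 7.24 ± 0.16 and Ccr2 by 5.61 ± 0.13 and 6.43 ± 0.14. In the WT-labelled libraries 4946 of 12750 genes were higher and 4982 lower (4379 by at least 1 on the log2 scale). In the KO-labelled ones 4818 were higher and 4753 lower (4158 by at least 1). Without scaling beyond the totals, the median log2 fold change of all genes shifted to -0.15 in both, so that changes are given relative to TMM scaling. Without it, 4064 were higher and 5730 lower in the WT-labelled (41.5% higher instead of 49.8%) and 3888 and 5611 in the KO-labelled libraries (40.9% instead of 50.3%). Here too more barcodes were kept at 48 h, 47.2 and 43.4% against 34.8 and 27.6% of effector ones in the WT-labelled and 34.1 and 37.5% against 23.1 and 17.2% in the KO-labelled libraries. A cluster with a median of 960.0 UMIs held 12.1 to 34.2% of the effector and 0 of the 48 h cells. With at least 1000 genes per cell, 9915 and 9559 genes changed. As in the first transfer experiment, time is not separated from the move from culture into mice.

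Of 52 G2/M genes, 50 fell and 1 rose in the WT-labelled libraries (adjusted p = 1.5e-39, and adjusted p = 0.113 with an estimated correlation). In the KO-labelled ones 51 fell and 1 rose (adjusted p = 1.9e-36, and adjusted p = 0.1 with an estimated correlation). Top2a was at -2.997 ± 0.086 and -2.836 ± 0.086 and Mki67 at -2.98 ± 0.09 and -2.80 ± 0.09. Of 42 S phase genes, 41 and 42 fell (adjusted p = 7.1e-30 and 1.85e-26, and adjusted p = 0.0976 and 0.0811 with an estimated correlation). Glycolysis genes had 19 of 21 lower and 1 higher in each label (adjusted p = 2.1e-13 and 3.6e-15, and adjusted p = 0.133 and 0.105 with an estimated correlation), with Tpi1 at -3.89 ± 0.08 and -3.52 ± 0.08. Cholesterol synthesis had 20 and 21 of 23 lower and 1 higher (adjusted p = 1.7e-10 and 1.3e-13, and adjusted p = 0.133 and 0.0811 with an estimated correlation). The unfolded protein response had 21 of 25 lower and 3 higher in each (adjusted p = 9.8e-10 and 2.1e-11, and adjusted p = 0.148 and 0.108 with an estimated correlation), with Xbp1 at -3.15 ± 0.07 and -3.03 ± 0.07. MYC and ribosome biogenesis genes had 24 of 29 lower in each, with 2 and 1 higher (adjusted p = 1.4e-04 and 1.2e-04, and adjusted p = 0.35 and 0.383 with an estimated correlation). Th2 effector genes had 11 lower and 7 higher, and 12 lower and 5 higher, of 22 (adjusted p = 1.0e-04 and 1.9e-06, and adjusted p = 0.0976 and 0.0811 with an estimated correlation). Regulatory T cell genes had 6 lower and 2 higher, and 8 lower and 1 higher, of 10 (adjusted p = 2.2e-04 and 1.8e-05, and adjusted p = 0.0976 and 0.0811 with an estimated correlation). Activation genes went both ways, 14 higher and 13 lower of 27 in the WT-labelled libraries (adjusted p = 0.0738) and 12 higher and 13 lower in the KO-labelled ones (adjusted p = 0.00245, and adjusted p = 0.0811 with an estimated correlation).

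Naive, memory and homing genes had 17 higher and 4 lower, and 18 higher and 4 lower, of 22 (adjusted p = 2.1e-14 and 1.5e-13, and adjusted p = 0.0976 and 0.0811 with an estimated correlation). Interferon-induced genes had 27 and 26 of 33 higher and 4 lower in each (adjusted p = 5.6e-08 and 5.4e-09, and adjusted p = 0.0976 and 0.0811 with an estimated correlation), with Slfn5 at 5.25 ± 0.10 and 4.72 ± 0.10. Handling stress genes had 12 higher and 7 lower, and 13 higher and 8 lower, of 22 (adjusted p = 2.0e-05 and 1.2e-04, and adjusted p = 0.137 and 0.12 with an estimated correlation), with Fos at 4.79 ± 0.11 and 4.31 ± 0.11. Ribosomal protein genes had 47 higher and 1 lower, and 38 higher and 2 lower, of 56 (adjusted p = 0.00407 and 0.0152, and adjusted p = 0.651 and 0.729 with an estimated correlation). The MondoA and arrestin-domain list had 5 of 7 higher in each (adjusted p = 0.0143 and 0.00236, and adjusted p = 0.133 and 0.0811 with an estimated correlation), with Arrdc4 at 1.39 ± 0.13 and 2.13 ± 0.11. Nfe2l2 rose by 1.05 ± 0.08 and 1.42 ± 0.09 and Bcl2l11, a proapoptotic gene, by 1.04 ± 0.08 and 0.64 ± 0.09. Bcl2 was at -1.77 ± 0.07 and -1.80 ± 0.07 and Hmox1 at -2.17 ± 0.15 in each. Blvrb was -0.04 ± 0.09 in the WT-labelled libraries (adjusted p = 0.673) and fell by 0.20 ± 0.09 in the KO-labelled ones (adjusted p = 0.0439, and 0.126 with DESeq2). That fall was -0.11 with all barcodes (adjusted p = 0.26) and -0.36 without scaling. Lists not past the camera threshold were oxidative phosphorylation (7 higher and 41 lower, and 17 higher and 21 lower, of 70), antioxidant and thiol genes (12 and 17, and 13 and 15, of 32), NRF2 targets (9 and 16 of 29 in each) and proapoptotic genes (8 and 10, and 7 and 9, of 23). Antiapoptotic genes (9 and 3, and 7 and 3, of 12), mitochondrially encoded genes (8 and 2, and 6 and 2, of 13), follicular helper genes (5 and 4, and 4 and 4, of 9) and Th1 genes (6 and 2, and 7 and 2, of 10) were not past it either. Adjusted over the list alone, counts differed only for S phase (42 lower) and ribosomal proteins (2 lower) in the WT-labelled libraries and for oxidative phosphorylation (16 higher) in the KO-labelled ones. Signs of median, mean and test differed for the antioxidant, proapoptotic and follicular helper lists in both labels, and for activation (median 0.35, mean -0.13) and Th1 (median 1.27, mean -0.10) in the WT-labelled one. All 11 T cell markers were higher at 48 h in each label (adjusted p = 8.7e-05 and 4.3e-05, and adjusted p = 0.363 and 0.336 with an estimated correlation). Monocyte or macrophage markers had 3 and 2 of 5 genes higher and 1 lower in each (adjusted p = 0.0144 and 0.0216, and adjusted p = 0.203 and 0.329 with an estimated correlation). Plasma cell markers had 4 and 5 of 5 lower (adjusted p = 0.00178 and 3.3e-04, and adjusted p = 0.202 and 0.205 with an estimated correlation).

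Time effects were set against each other across genes, which are not independent replicates. The first transfer experiment and the WT-labelled time effect had Pearson r = 0.867 and Spearman rho = 0.828 over 12354 genes. There were 3501 genes higher in both (1694.1 by chance), 3454 lower in both (1625.8) and 341 in opposite directions (3322.3). WT-labelled and KO-labelled time effects, from 1 experiment and 1 fit, had r = 0.948 and rho = 0.957, with 4364 genes higher in both, 4407 lower in both and 14 in opposite directions. First transfer and in vivo time effects had r = 0.392 and rho = 0.453 over 11718 genes, and 2247 were higher in both (1322.3 by chance), 2152 lower in both (1333.2) and 1230 in opposite directions (2687.0). With no filter on low counts this last r was 0.237, over 1.5 times lower, in edgeR and in DESeq2.

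To ask what differs between the genotype labels before transfer, KO-labelled effector libraries were compared with WT-labelled ones. Ifitm1 (229.7 against 81.0 CPM) was higher by 1.501 ± 0.093, the metallothionein genes Mt3 and Mt2 by 1.22 ± 0.11 and 0.97 ± 0.08, and Lgals3 by 1.01 ± 0.10. So were Me1 (1.39 ± 0.19), Arrdc4, an arrestin-domain relative of Txnip (0.76 ± 0.15, adjusted p = 0.0104), and Foxp3, the transcription factor of regulatory T cells (0.86 ± 0.18). Lower were Tcf7 (-0.80 ± 0.20), Klf2 (-0.79 ± 0.12), a transcription factor of quiescence and trafficking, Isg20 (-0.77 ± 0.16), Penk (-0.66 ± 0.12) and Foxp1 (-0.61 ± 0.10). Trac, which encodes the constant part of the receptor alpha chain, was higher by 0.70 ± 0.07. Chosen after their values were seen, Trbc1 (0.51 ± 0.08, adjusted p = 0.00115), Trbv13-2 (0.60 ± 0.07) and Polr3gl (0.42 ± 0.07, adjusted p = 0.00514), whose start lies 20 kb from that of Txnip, were also higher, and Trbc2 was not past the threshold (-0.13 ± 0.07, adjusted p = 0.283). Nfe2l2 (-0.31 ± 0.10, adjusted p = 0.0934), Blvrb (0.27 ± 0.09, adjusted p = 0.0967), Hmox1 (0.17 ± 0.12), Bcl2l11 (0.05 ± 0.10) and Bcl2 (0.01 ± 0.07) were not past it either. Genes past the threshold numbered 237 higher and 182 lower of 12750, 54 by at least 1 on the log2 scale, and 272 and 136 without scaling (66.7% higher instead of 56.6%).

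Between effector libraries, naive, memory and homing genes had 4 of 22 lower and none higher (adjusted p = 0.00275). Oxidative phosphorylation had 3 of 70 lower (adjusted p = 9.0e-10), with Ndufb6 at -0.36 ± 0.07 and Ndufs3 at -0.31 ± 0.07. G2/M had 3 of 52 lower (adjusted p = 6.6e-06) and S phase 1 of 42 lower (adjusted p = 0.0271). Antioxidant and thiol genes had 3 of 32 lower (adjusted p = 0.0271), with Prdx1 at -0.36 ± 0.09 and Gclm at -0.29 ± 0.08, and MYC and ribosome biogenesis 0 of 29 (adjusted p = 0.018). Each of these 6 had adjusted p = 0.811 with an estimated correlation. The other lists had 2 higher and 1 lower of 27 (activation), 2 higher of 21 (glycolysis), 3 lower of 33 (interferon), 1 higher of 13 (mitochondrially encoded), and 1 higher of 7 (MondoA and arrestin-domain). There were also 1 higher and 2 lower of 29 (NRF2 targets), 1 lower of 9 (follicular helper), 1 higher of 10 (Th1), 1 higher of 22 (Th2 effector) and 1 higher of 10 (regulatory T cell), and 0 past the threshold for antiapoptotic, proapoptotic, cholesterol, handling stress, ribosomal and unfolded protein response genes. Adjusted over the list alone, oxidative phosphorylation had 9 lower, handling stress 1 higher and 4 lower, interferon 2 higher and 4 lower and NRF2 targets 4 higher and 4 lower. Activation then had 2 higher and 2 lower, Th2 effector 2 higher and 1 lower, regulatory T cell 2 higher, and follicular helper 2, antioxidant 4 and naive, memory and homing genes 5 lower. Median, mean and test differed in sign for antiapoptotic, proapoptotic, NRF2 target, ribosomal and Th2 effector lists. B cell markers had 2 of 10 higher (adjusted p = 0.0104, and adjusted p = 0.372 with an estimated correlation) and dendritic cell markers 1 of 5 higher (adjusted p = 0.00325, and adjusted p = 0.329 with an estimated correlation). A cluster with a median of 960.0 UMIs and 0.33% mitochondrial UMIs held 33.6 and 34.2% of the WT-labelled and 32.5 and 12.1% of the KO-labelled effector cells, so that KO-labelled replicate 2 stood apart. The share of barcodes kept was lower in the KO-labelled effector libraries (23.1 and 17.2%) than in the WT-labelled ones (34.8 and 27.6%). The count of 419 genes moved to 263 with at most 5% mitochondrial UMIs, 275 at equal depth, 918 without the filter on low counts, 224 with DESeq2, also without that filter, and 62 for changes of at least 1.2-fold. Without KO-labelled effector replicate 2, adjusted p was 0.128 for Arrdc4, 0.153 for Foxp3, 0.169 for Ndufb6, 0.293 for Ndufs3, 0.332 for Gclm and 0.26 for Prdx1. Without replicate 1 of that group it was 0.372 for Tcf7, which had -0.47, 0.113 for Isg20, 0.0847 for Polr3gl and 0.0591 for Klf2. Without WT-labelled effector replicate 1, Isg20 had -0.37 (adjusted p = 0.0818), Prdx1 -0.16 (adjusted p = 0.222), Ndufs3 -0.20 (adjusted p = 0.18) and Penk -0.45 (adjusted p = 0.0642). With DESeq2 Penk kept -0.66 with an adjusted p of 0.11, and Me1 and Foxp3 were given no adjusted p. The count was 1394 without WT-labelled effector replicate 2, 174 without replicate 1 of that group, and 100 and 156 without KO-labelled effector replicates 1 and 2.

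At 48 h the KO-labelled libraries had higher Arrdc4 (1.499 ± 0.10, 21.0 against 7.43 CPM, adjusted p = 1.4e-07), Polr3gl (0.98 ± 0.06, 54.7 against 27.8 CPM, adjusted p = 1.4e-07) and Txnip (0.93 ± 0.07). Plac8 (1.04 ± 0.14), Ifitm3 (1.00 ± 0.12), Lgals3 (0.94 ± 0.09), Cyp11a1 (0.93 ± 0.09) and the receptor constant genes Trdc (0.97 ± 0.07) and Trbc1 (0.73 ± 0.08, 25400 against 15300 CPM) were higher as well. Chosen after their values were seen, Trac (0.56 ± 0.07), Trbv13-2 (0.69 ± 0.06) and Lix1l (1.21 ± 0.28), a neighbour of Txnip, were higher and Trbc2 was not past the threshold (-0.01 ± 0.07, adjusted p = 0.968). Genes of the activation and handling stress lists that were lower included Nr4a1 by -1.80 ± 0.09 (adjusted p = 1.0e-08), Nr4a2 by -1.37 ± 0.11, Dusp1 by -1.12 ± 0.10, Fos by -0.88 ± 0.09, Myc by -0.87 ± 0.08 and Cd69 by -0.80 ± 0.09. Gadd45b, on neither list, was lower by -1.08 ± 0.08. The cytokine genes Areg (-2.69 ± 0.23), Ccl1 (-2.22 ± 0.37) and Csf2 (-0.55 ± 0.09) were lower too. Bcl2l11 was lower by -0.36 ± 0.08 (adjusted p = 0.0162), while Hmox1 (0.17 ± 0.19), Blvrb (0.11 ± 0.09), Nfe2l2 (0.06 ± 0.08) and Bcl2 (-0.01 ± 0.07) were not past the threshold. With DESeq2 adjusted p was 0.233 for Bcl2l11, 0.682 for Ccl1 and 0.0642 for Lix1l. Ccl1 had -3.90 without KO-labelled 48 h replicate 2. Tested for a change of at least 1.2-fold, Csf2 kept -0.55 with an adjusted p of 0.056.

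**Figure D2:**
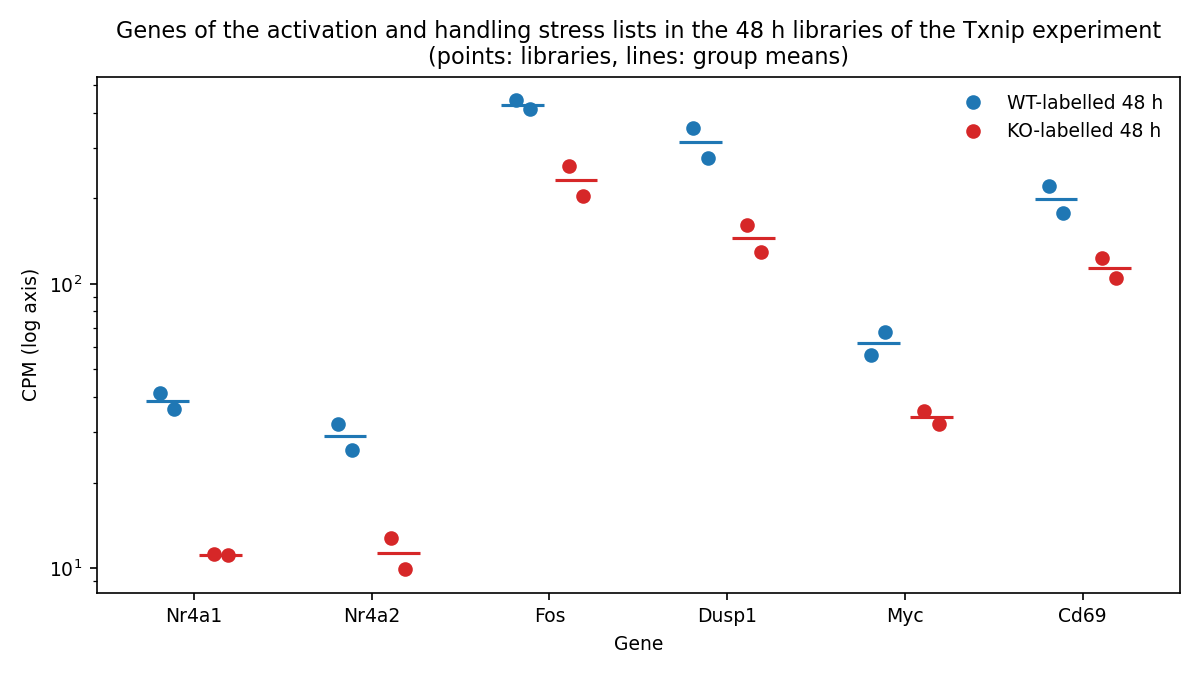
CPM (vertical log axis) of 6 genes of the activation and handling stress lists (horizontal axis) in the 48 h libraries of the Txnip experiment, with points for libraries and lines for group means. Mean Nr4a1 was 38.8 CPM in the WT-labelled and 11.2 CPM in the KO-labelled libraries, and mean Dusp1 316 and 145 CPM.

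Among lists, 12 of 22 naive, memory and homing genes were lower and 1 higher at 48 h in the KO-labelled libraries (adjusted p = 2.8e-16, and adjusted p = 0.0434 with an estimated correlation), with Ccr7 at -0.70 ± 0.07 and S1pr1 at -0.67 ± 0.07. Activation genes had 10 lower and 1 higher of 27 (adjusted p = 2.3e-14, and adjusted p = 0.0197 with an estimated correlation). The MondoA and arrestin-domain list had 2 of 7 higher, Arrdc4 and Txnip (adjusted p = 9.4e-07, and adjusted p = 0.0434 with an estimated correlation). Handling stress genes had 9 of 22 lower (adjusted p = 1.5e-15, and adjusted p = 0.0532 with an estimated correlation). S phase genes had 4 of 42 higher (adjusted p = 6.2e-09, and adjusted p = 0.388 with an estimated correlation), among them Cdc6 (0.70 ± 0.13, and 0.32, adjusted p = 0.721, with cycling clusters left out). G2/M genes had 4 of 52 higher (adjusted p = 6.4e-05, and adjusted p = 0.685 with an estimated correlation). Ribosomal proteins (0 of 56, adjusted p = 6.4e-05), mitochondrially encoded genes (0 of 13, adjusted p = 0.0128), cholesterol synthesis (1 of 23 lower, adjusted p = 0.00125), antiapoptotic genes (1 of 12 lower, adjusted p = 0.0101) and Th2 effector genes (5 lower and 2 higher of 22, adjusted p = 0.00207) were past the test as lower, with adjusted p = 0.685, 0.685, 0.388, 0.153 and 0.0941 with an estimated correlation. Th1 genes were past it as higher (1 of 10, adjusted p = 0.0082, and adjusted p = 0.183 with an estimated correlation). The other lists had 1 higher and 1 lower of 21 (glycolysis), 3 higher of 33 (interferon), 1 higher of 29 (NRF2 targets), 1 lower of 23 (proapoptotic), 1 lower of 9 (follicular helper), 1 higher of 10 (regulatory T cell), 1 higher and 2 lower of 25 (unfolded protein response) and 0 past the threshold for antioxidant, MYC and oxidative phosphorylation genes. Adjusted over the list alone, naive, memory and homing genes had 15 lower and 2 higher, activation 13 lower and 3 higher, handling stress 11 lower, S phase 9 and G2/M 5 higher and Th2 effector 8 lower. Antiapoptotic and cholesterol genes then had 4 lower each, NRF2 targets 3 higher, glycolysis 2 higher and 1 lower, interferon and Th1 genes 4 higher and 1 lower each, regulatory T cell genes 2 higher and 2 lower and follicular helper genes 1 higher and 1 lower. Signs of median, mean and test differed for the interferon, proapoptotic, follicular helper, regulatory T cell and unfolded protein response lists. Gamma-delta T cell markers had 1 of 3 higher (adjusted p = 3.1e-04) and monocyte or macrophage markers 1 of 5 lower (adjusted p = 0.009), each with adjusted p = 0.162 with an estimated correlation.

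In all, 218 of 12750 genes were higher and 281 lower in the KO-labelled 48 h libraries, 84 by at least 1 on the log2 scale, and 269 and 226 without scaling (54.3% higher instead of 43.7%). Of the genes called between genotype labels at both times, 53 were higher in both (4.1 by chance), 26 lower in both (4.0) and 7 in opposite directions (8.3), while the fold changes had r = 0.185 and rho = 0.126. This r was 0.031 with no filter on low counts, 0.043 with DESeq2, also without that filter, 0.342 with only the groups compared, 0.101 without KO-labelled 48 h replicate 1 and 0.134 without WT-labelled effector replicate 2. Within 10 Mb of Txnip, 11 of 223 tested genes were past the threshold at 48 h (4.9%, against 3.9% elsewhere, Fisher's exact test p = 0.384). In effector libraries it was 10 of 223 (4.5% against 3.26%, Fisher's exact test p = 0.338). Within 1 Mb it was 4 of 33 genes at 48 h, Polr3gl and Lix1l among them, and 2 of 33 in effector libraries, which was not tested. As a list these neighbours had a p by camera (limma, on the edgeR fit) of 0.311 at 48 h and 0.775 in effector libraries. The share of barcodes kept was 34.1 and 37.5% in the KO-labelled and 47.2 and 43.4% in the WT-labelled 48 h libraries. Among cells with at least 3000 UMIs, those with under 0.5% mitochondrial UMIs made up 4.01 and 3.36% against 2.67 and 2.29%. On simulated data with 12453 genes tested, all 100 genes changed 2-fold and 96% of those changed 1.5-fold were recovered, with 8.4% false calls. The count of 499 genes was 768 with no filter on low counts, 262 with DESeq2, also without that filter, 328 at equal depth and 132 for changes of at least 1.2-fold. It was 160, 326 and 189 without WT-labelled 48 h replicate 1 and KO-labelled 48 h replicates 1 and 2.

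Whether the change over 48 h differed between the genotype labels was tested as an interaction, in which positive values mean a larger rise or smaller fall in the KO-labelled libraries. Nr4a1 (-2.02 ± 0.25, adjusted p = 0.00165), Atf3 (-1.94 ± 0.32), Rgs2 (-1.91 ± 0.42), Nr4a2 (-1.36 ± 0.29), Hk2 (-0.97 ± 0.13) and Myc (-0.84 ± 0.12) had negative interactions, as did Areg (-2.16 ± 0.41). Batf3 (1.43 ± 0.22, adjusted p = 0.0034), Isg20 (0.99 ± 0.20), Txnip (0.85 ± 0.12, adjusted p = 0.0024), Ccr2 (0.83 ± 0.19), Igfbp4 (0.81 ± 0.12), Ccnb2 (0.78 ± 0.16) and Cdc6 (0.78 ± 0.15) had positive ones. Polr3gl, chosen after its values were seen, was at 0.56 ± 0.10 (adjusted p = 0.00933), and Trbc1 (0.22 ± 0.11, adjusted p = 0.372) and Trac (-0.14 ± 0.10, adjusted p = 0.582), chosen likewise, were not past the threshold. Arrdc4 (0.74 ± 0.18, adjusted p = 0.0616), Nfe2l2 (0.38 ± 0.13), Bcl2l11 (-0.40 ± 0.13, adjusted p = 0.139), Blvrb (-0.16 ± 0.12), Bcl2 (-0.03 ± 0.09) and Hmox1 (-0.0013 ± 0.26) were not past it. With cycling clusters left out Batf3 (1.49, adjusted p = 0.294) and Nr4a2 (-1.51, adjusted p = 0.0551) kept their size but not the call. Igfbp4 had 0.25 (adjusted p = 0.323), Cdc6 0.38 (adjusted p = 0.651), Ccr2 0.57 (adjusted p = 0.081) and Ccnb2 1.23 (adjusted p = 0.0461). With at most 5% mitochondrial UMIs adjusted p was 0.0887 for Rgs2, 0.0811 for Areg, 0.0565 for Ccnb2 and 0.0558 for Polr3gl. It was 0.172 for Nr4a2, 0.199 for Ccr2 and 0.0802 for Batf3. Without 1 library, Ccr2 had 0.49 (KO-labelled effector replicate 1) and Isg20 0.58 (WT-labelled effector replicate 1). Nr4a2, Ccnb2, Rgs2, Cdc6, Polr3gl, Areg, Atf3, Ccr2 and Isg20 kept direction but lost the call in some fits without 1 library. Rgs2 had -1.53 without KO-labelled effector replicate 1 and Areg -1.67 without replicate 2 of that group. Without KO-labelled 48 h replicate 2, Ccnb2 had 0.60 and Atf3 -1.54. With DESeq2 adjusted p was 0.143 for Isg20 and 0.404 for Ccr2, and Areg was given none. In all, 69 of 12750 genes were past it with a positive and 87 with a negative interaction, 26 of them by at least 1 on the log2 scale.

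G2/M genes had 4 of 52 positive interactions and S phase genes 5 of 42 (adjusted p = 1.1e-11 for each, and adjusted p = 0.369 and 0.326 with an estimated correlation). Oxidative phosphorylation had 1 of 70 positive (adjusted p = 2.8e-09, and adjusted p = 0.388 with an estimated correlation) and antioxidant genes 0 of 32 (up, adjusted p = 0.00581, and adjusted p = 0.521 with an estimated correlation). Negative as lists were handling stress (4 of 22, adjusted p = 2.9e-06, and adjusted p = 0.261 with an estimated correlation), activation (4 of 27, adjusted p = 6.2e-04, and adjusted p = 0.261 with an estimated correlation) and cholesterol synthesis (1 of 23, adjusted p = 4.5e-05, and adjusted p = 0.326 with an estimated correlation). So were ribosomal proteins (0 of 56, adjusted p = 5.0e-04, and adjusted p = 0.531 with an estimated correlation), mitochondrially encoded genes (0 of 13, adjusted p = 6.2e-04, and adjusted p = 0.388 with an estimated correlation) and Th2 effector genes (1 of 22, adjusted p = 0.00843, and adjusted p = 0.261 with an estimated correlation). The same held for antiapoptotic genes (0 of 12, adjusted p = 0.0132, and adjusted p = 0.261 with an estimated correlation) and naive, memory and homing genes (4 negative and 1 positive of 22, adjusted p = 0.00843, and adjusted p = 0.326 with an estimated correlation), whose mean was 0.02 and median -0.13. The other lists had 4 positive of 33 (interferon), 1 positive of 7 (MondoA and arrestin-domain), 1 negative of 21 (glycolysis), 2 negative of 25 (unfolded protein response) and 0 for MYC, NRF2 target, proapoptotic, follicular helper, Th1 and regulatory T cell genes. Adjusted over the list alone, S phase had 14 and G2/M 12 positive interactions, and naive, memory and homing genes 9 and handling stress 8 negative ones. There were then also 6 negative and 1 positive for activation, 4 negative for cholesterol, 7 positive and 2 negative for interferon, 4 positive for naive, memory and homing genes and 2 positive for the MondoA list. NRF2 targets had 2 positive and 1 negative, glycolysis 1 of each, follicular helper genes 1 positive, and mitochondrially encoded and regulatory T cell genes 1 negative each. Median, mean and test also differed in sign for the MondoA, proapoptotic and unfolded protein response lists. B cell markers had 2 of 10 negative (adjusted p = 2.3e-05, and adjusted p = 0.778 with an estimated correlation). The total of 156 was 461 with no filter on low counts, 79 at equal depth, 90 with at most 5% mitochondrial UMIs and 21 for changes of at least 1.2-fold. Leaving out 1 library moved it to 93 (WT-labelled effector replicate 1), 755 (replicate 2 of that group), 44 and 53 (KO-labelled effector replicates 1 and 2), 53 (WT-labelled 48 h replicate 1) and 36 (KO-labelled 48 h replicate 2).

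In cells primed in vivo, day 11 was compared with day 7 after naive cells were transferred. Klf2 rose by 3.41 ± 0.10, S1pr1 by 3.19 ± 0.11, Il7r by 3.15 ± 0.20, Tsc22d3, a glucocorticoid-induced gene, by 3.39 ± 0.36 and Rflnb by 3.15 ± 0.17. Chek1, a checkpoint kinase, fell by 4.80 ± 0.17, Shmt1 by 4.51 ± 0.15, and Uhrf1 by 4.41 ± 0.20, with Mcm5 at -3.50 ± 0.14. Myc (-2.67 ± 0.13), Il2ra (-2.31 ± 0.12), Tnfrsf4 (-3.07 ± 0.11) and Hk2, the first enzyme of glycolysis (-3.06 ± 0.12), fell as well, and so did Igkc, an immunoglobulin light chain constant gene (-4.16 ± 0.41). Nfe2l2 rose by 0.95 ± 0.10 and Arrdc4 by 0.47 ± 0.13 (adjusted p = 0.0137), while Bcl2 (-0.62 ± 0.08) and Hmox1 (-0.62 ± 0.21, adjusted p = 0.0344) fell. Blvrb (0.23 ± 0.09, adjusted p = 0.0623) and Bcl2l11 (-0.15 ± 0.24, adjusted p = 0.609) were not past the threshold. Bcl2l11 had 0.29 (adjusted p = 0.035) without day 7 replicate 1. Hmox1 had -0.22 (adjusted p = 0.0587) without day 7 replicate 2 and -0.93 without replicate 1. With other cell types kept Hmox1 had -0.26 (adjusted p = 0.244) and Igkc -1.29 (adjusted p = 0.105), and with cycling clusters left out Igkc had -1.61. With all barcodes Hmox1 had -0.33 and Igkc -1.35, with at most 5% mitochondrial UMIs Hmox1 had -0.99 and Bcl2 -0.28, and without scaling Hmox1 had -0.38 and Bcl2 -0.39. The adjusted p of Arrdc4 was 0.0658 with DESeq2. Of 13427 genes tested, 4244 were higher and 4410 lower, 3471 by at least 1 on the log2 scale. Kept cells had a median of 11789 and 12137 UMIs on day 7 and 6811 and 5688.5 on day 11, and the median mitochondrial share of all barcodes was 4.19 and 3.84% against 5.35 and 5.09%, so that time and RNA quality are not separated here. A cluster with a median of 1829 UMIs held 2158 cells of day 11 replicate 2, against 108 of replicate 1 and 8 and 14 on day 7. Barcodes listed in both day 11 libraries, described below, had a median of 1857 UMIs in replicate 2. Whether they make up that cluster was not tested. The count of 8654 genes was 8613 with at least 1000 genes per cell and 8452 with at most 5% mitochondrial UMIs. Without scaling 5897 were higher and 3341 lower (63.8% higher instead of 49.0%), with the median of all genes at 0.27, so that changes are given relative to TMM scaling.

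MYC and ribosome biogenesis genes all fell (29 of 29, adjusted p = 8.4e-36, and adjusted p = 0.519 with an estimated correlation), with Ncl at -2.19 ± 0.09. S phase genes had 41 of 42 lower (adjusted p = 1.3e-31, and adjusted p = 0.621 with an estimated correlation). With adjusted p = 0.621 with an estimated correlation each, oxidative phosphorylation had 66 of 70 lower (adjusted p = 6.0e-13), G2/M 44 lower and 4 higher of 52 (adjusted p = 3.5e-08), and cholesterol synthesis 22 of 23 lower (adjusted p = 4.6e-08). Likewise with adjusted p = 0.621 with an estimated correlation, glycolysis had 17 lower and 1 higher of 21 (adjusted p = 6.7e-05), ribosomal proteins 39 lower and 1 higher of 56 (adjusted p = 6.6e-05) and the unfolded protein response 17 lower and 6 higher of 25 (adjusted p = 0.0172). Again with adjusted p = 0.621 with an estimated correlation, interferon-induced genes had 24 higher and 1 lower of 33 (adjusted p = 7.5e-07) and the MondoA and arrestin-domain list 6 higher and 1 lower of 7 (adjusted p = 0.024). Activation genes had 20 lower and 3 higher of 27 (adjusted p = 6.1e-08) and naive, memory and homing genes 19 higher and 1 lower of 22 (adjusted p = 2.5e-11), both with adjusted p = 0.519 with an estimated correlation. Antioxidant genes had 21 lower and 4 higher of 32 (adjusted p = 0.0226, and adjusted p = 0.723 with an estimated correlation). Not past the camera threshold were Th2 effector genes (7 higher and 5 lower of 16), handling stress (9 and 9 of 21), antiapoptotic (5 and 4 of 13), proapoptotic (8 and 9 of 24), NRF2 targets (7 and 13 of 27), mitochondrially encoded (2 and 0 of 13), follicular helper (4 and 2 of 10), Th1 (4 and 5 of 12) and regulatory T cell genes (1 and 6 of 10). Adjusted over the list alone, oxidative phosphorylation had 68, ribosomal proteins 40, antioxidant genes 22 and NRF2 targets 14 lower, antioxidant and G2/M genes 5 higher each and mitochondrially encoded genes 1 higher. Median, mean and test differed in sign for the antiapoptotic, handling stress and proapoptotic lists. On simulated data with 13182 genes tested, all 100 genes changed 2-fold and 75% of those changed 1.5-fold were recovered, with 8.9% false calls. Here too only 200 genes changed in the simulation, far fewer than were called in the data. The labels disagree about the sort, since the sample characteristics name CD4 and high CD44 for these libraries and the protocol names the antibody to the transgenic receptor. In the other experiments the reverse holds. T cells of the recipient mice may thus be among the cells measured after transfer, and their share stays open.

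**Figure D3:**
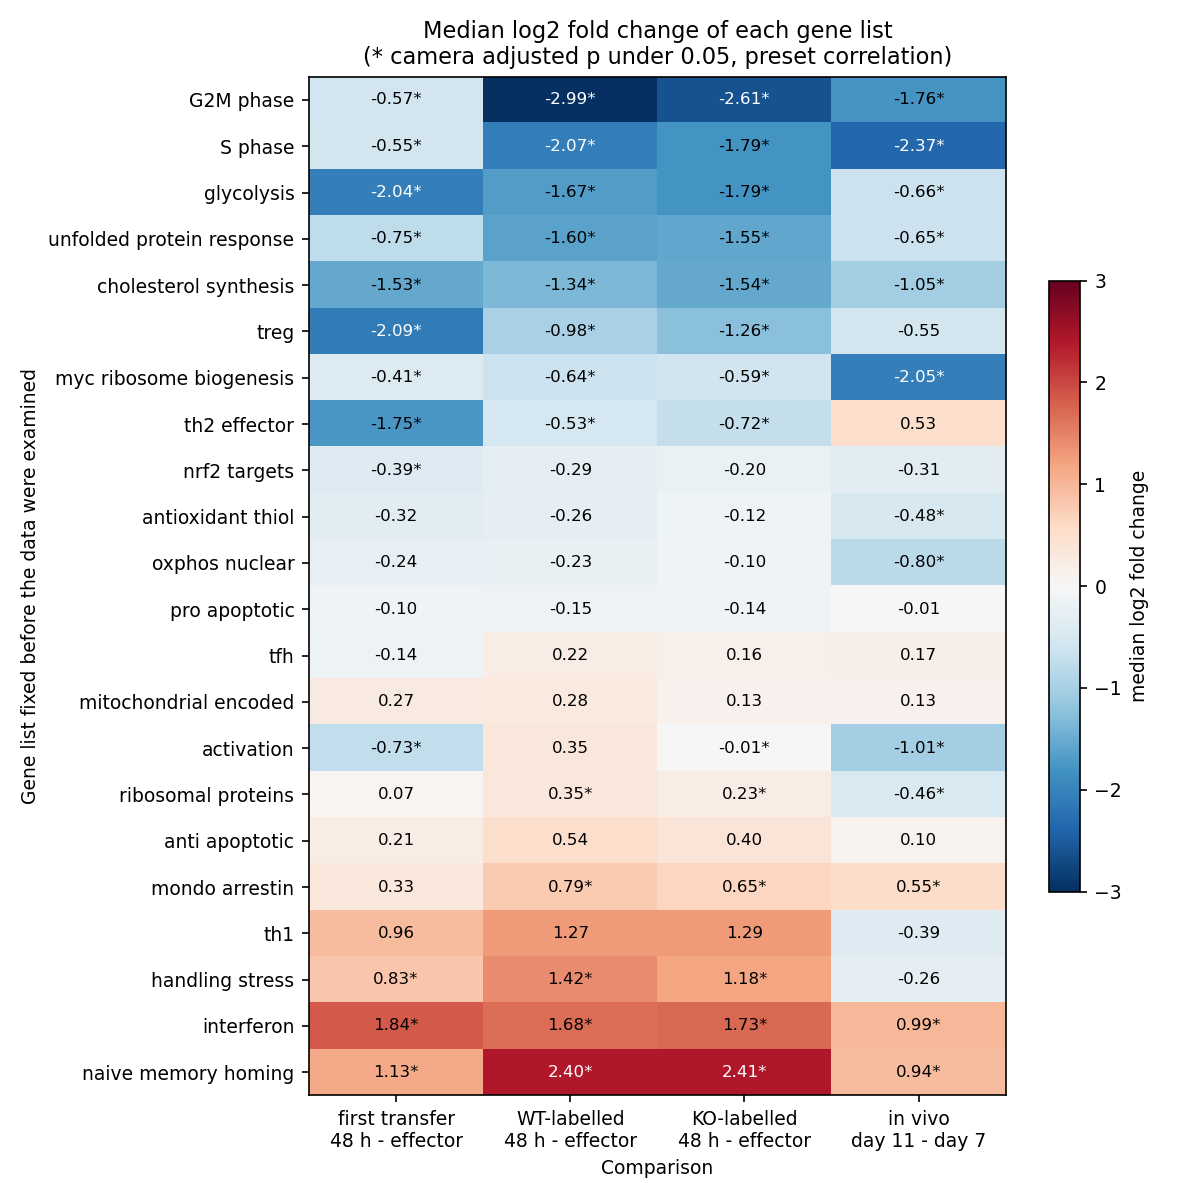
Median log2 fold change (colour and number) of the 22 gene lists (vertical axis) in 4 comparisons over time (horizontal axis), with asterisks for camera adjusted p under 0.05 at the preset correlation. The G2/M median was -2.99 in the WT-labelled libraries over 48 h, and the MYC and ribosome biogenesis median was -2.05 in vivo.

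Cells of other types were looked for in clusters that carry their markers. No cluster met the rule for other cell types among effector cells or in the first transfer experiment. The 0 cells give an upper limit of 0.312% per library (exact 95% interval), which covers only cells whose cluster meets the rule. The WT-labelled 48 h libraries held 0.048 and 0.198% and the KO-labelled ones 0.591 and 0.303%, and the in vivo libraries 1.47 and 1.61% on day 7 and 1.85 and 1.35% on day 11. Those cells were left out of the sums, but RNA from other cells can remain. The marker lists hold none for regulatory T cells, so that such cells cannot be called. A cluster with Ikzf2 and Foxp3 among its leading genes held 72 and 67 cells at 48 h in the first transfer experiment. Another held 106 and 98 WT-labelled and 101 and 133 KO-labelled 48 h cells. Neither held effector cells, and both stayed in the sums. An in vivo cluster of 160 cells with Nkg7 and Tcrg-C4 held 2 markers of other types and stayed too. Among marker lists, median, mean and test differed in sign for gamma-delta T cells and natural killer cells in the first transfer experiment and for dendritic, natural killer and platelet lists in vivo. They did so for gamma-delta T cells over time in each genotype label, for B, dendritic and stromal cells over time in the WT-labelled one, and for gamma-delta T, monocyte and stromal cells between effector libraries. The T cell list did so at 48 h and, with dendritic, erythroid and monocyte lists, in the interaction. Neutrophil markers were higher on day 11 for 5 of 5 genes and plasma cell markers lower for 5 of 7, and neither list was past the camera test (adjusted p = 0.204 for each).

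The day 11 libraries listed 3380 barcodes in common, of 7712 in replicate 1, while other pairs of libraries shared 42 at most. For the shared barcodes, replicate 2 held a median of 0.236 times the UMIs of replicate 1, and the cells' profiles correlated at 0.501 against -0.001 for random pairs of barcodes. Over these barcodes the UMIs of the 2 libraries had a Spearman correlation of 0.95, and 3372 barcodes held fewer UMIs in replicate 2. The ratio lay between 0.201 and 0.253 from the 5th to the 95th percentile. These values argue against different cells that share a barcode by chance. The 2 day 11 libraries are thus not fully independent replicates, and the in vivo p-values can be too small. How these barcodes came into both libraries was not settled. With each shared barcode kept only in the library where it held more UMIs, which left 6026 of 6031 cells in replicate 1 and 7611 of 10595 in replicate 2, 8561 genes changed between day 7 and day 11, against 8654 otherwise. With shared barcodes left out of both libraries, which left 2980.0 and 7603 cells, 8159 changed, and Arrdc4 had 0.35 (adjusted p = 0.0672).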

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

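The interaction test was fixed before the data were examined. Of the tests of explanations, all but those of the cluster mix and of cells with little Trbc1 were chosen only after the result was seen.

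The change with time differed between the genotype labels for 156 genes by the interaction test. Among those named, the difference was 0.85 for Txnip, -2.02 for Nr4a1, -1.94 for Atf3, -1.91 for Rgs2, -1.36 for Nr4a2, -0.97 for Hk2, -0.84 for Myc and -2.16 for Areg on the log2 scale. It was 1.43 for Batf3, 0.99 for Isg20, 0.83 for Ccr2, 0.81 for Igfbp4, 0.78 for Ccnb2, 0.78 for Cdc6 and 0.56 for Polr3gl. Of these, Nr4a2, Ccnb2, Rgs2, Cdc6, Polr3gl, Areg, Atf3, Ccr2 and Isg20 lost the call in some fits without 1 library. Batf3 and Igfbp4 lost it with cycling clusters left out. The day 11 libraries listed 3380 barcodes in common, a signal in the barcode lists that only alternatives used.

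Txnip, Polr3gl and Arrdc4 were higher in the KO-labelled 48 h libraries. The tables argue against a swap of the 48 h labels, since only 8.14% of the genes called at both times went in opposite directions (7 of 86, 95% interval 3.34 to 16.05, exact binomial p = 1.5e-16). Genes are not independent replicates, so that this interval is too narrow and this p too small. For Txnip and Polr3gl, alleles of another strain around the locus cannot be told apart from other causes, since the odds ratio within 10 Mb was 1.28 (0.625 to 2.358, Fisher's exact test p = 0.3839), nor can a swap of all 8 labels, with Txnip at 0.075 among effector libraries. No test was made of such alleles for Arrdc4, on another chromosome. The genotype itself stays open and untested, since the tags may lie outside the deleted part.

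Of the activation and handling stress lists, 18 genes were past the threshold as lower in the KO-labelled 48 h libraries, so that their median of -0.634 is set by that choice. A heat-shock response during handling cannot be told apart from genotype, since 8 heat-shock genes, at a median of -0.029, spread too widely (standard deviation 0.64). The mix of clusters did differ. One cluster held 1594 and 1544 WT-labelled against 848 and 906 KO-labelled cells, and another 1083 and 1240 against 1313 and 1623. The tables argue against this mix as the source of the fall of these 18 genes, since it was past 0.5 of its value over all cells in 6 of 7 clusters. Time or handling between preparations cannot be told apart from genotype. The same genes had a median log2 ratio of CPM of 1.96 ± 0.255 between the WT-labelled 48 h libraries and those of the first transfer experiment. The genotype stays open and is confounded with preparation.

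Trbc1 and Trac were higher in the KO-labelled libraries at both times, while Trbc2 was not past the threshold at either (-0.13 and -0.01). The tables argue against more cells with little Trbc1 in the WT-labelled libraries. Cells under 0.1 of the median Trbc1 level differed by 0.96 percentage points at most. The prediction was at least 30 points with equal median cells if they were the cause, and under 10 if not. The median cell at 48 h had 14229 CPM in the WT-labelled and 23455 CPM in the KO-labelled libraries. Cells without the transgenic receptor that still hold Trbc1 RNA would not be seen by this test, so that their share stays open. The tables argue against more T cell RNA of every kind, with 9 other T cell markers at a median of -0.012 ± 0.062 at 48 h and -0.054 ± 0.039 in effector libraries. A different dose of the receptor transgene cannot be told apart from genotype, with an interaction for Trbc1 at adjusted p = 0.3721 in edgeR. The genotype stays open and untested.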

How the results depend on the processing

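All tests in this part with other limits on genes or mitochondrial UMIs, or without scaling, were chosen only after the result was seen, as were those that dropped shared barcodes. With each library left out, the lone library of its group was assumed to vary like the others. Of 2783 values of named genes under other alternatives 2665 kept direction and side of the threshold, 84 lost and 11 gained the call and 23 changed sign; with a library left out these were 1081, 75, 8 and 12 of 1176. No gene called in the report changed sign. Where a value below moved, the cause was not tested, except that a test of at least 1.2-fold asks for more and equal depth leaves fewer counts.

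Counts between KO-labelled and WT-labelled libraries, effector and 48 h, were 224 and 262 with DESeq2, which was run without the filter on low counts. For effector, 48 h and the interaction they were 918, 768 and 461 with no filter on low counts, 275, 328 and 79 at equal depth and 62, 132 and 21 for at least 1.2-fold. With at most 5% mitochondrial UMIs, effector and interaction had 263 and 90.0. With a library left out, counts were 7467 to 8788 (first transfer), 9168 to 10024 (WT-labelled time), 8722 to 9930.0 (KO-labelled time), 100.0 to 1394 (effector), 160.0 to 665 (48 h), 36 to 755 (interaction) and 6803 to 9709 (in vivo). In that order Txnip ranged over 2.257 to 2.608, 3.455 to 3.695, 4.334 to 4.505, -0.036 to 0.202, 0.872 to 0.982, 0.725 to 0.959 and 2.018 to 2.177, and gene lists past camera over 12 to 14, 13 to 14, 14 to 14, 5 to 7, 11 to 12, 12 to 14 and 12 to 13. Txnip in effector libraries turned to -0.036 and -0.017 without WT-labelled replicate 2 and KO-labelled replicate 1.

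Values that changed sign, none past the threshold in the report, were as follows. With all barcodes: Arrdc4 0.006 (first transfer), Blvrb 0.044 (WT-labelled time), Bcl2l11 -0.045 and Bcl2 -0.022 (effector), Hmox1 -0.276 and Bcl2 0.039 (48 h), Bcl2 0.061 (interaction) and Blvrb -0.001 (in vivo). Arrdc4 had 0.196 with cycling clusters left out (first transfer). At equal depth Bcl2 had 0.017 (48 h) and 0.011 (interaction). With other limits on cells, Bcl2 had -0.001 (effector) and 0.021 (48 h), Bcl2l11 -0.052 (effector) and 0.05 (in vivo) and Hmox1 0.008 (interaction). Without scaling Bcl2 and Trbc2 had 0.016 (48 h), Hmox1 0.001 (interaction) and Bcl2l11 0.074 (in vivo). Hmox1 had 0.002 (interaction) with DESeq2 and with no filter. With a library left out, Blvrb ranged over -0.162 to 0.095 (WT-labelled time), Hmox1 over -0.02 to 0.363 and Bcl2 over -0.004 to 0.03 (effector), Bcl2 over -0.091 to 0.064 and Trbc2 over -0.031 to 0.003 (48 h), Hmox1 over -0.199 to 0.181 and Bcl2 over -0.104 to 0.052 (interaction) and Bcl2l11 over -0.509 to 0.292 (in vivo).

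Gene lists past the test with an estimated correlation numbered 0 (first transfer), 0 (WT-labelled time), 0 (KO-labelled time), 0 (effector), 3 (48 h), 0 (interaction) and 0 (in vivo). With fry they were 21 (WT-labelled time), 0 (effector), 6 (48 h) and 3 (interaction), and with cycling clusters left out 2 (effector). By fry in either direction, which asks whether any of them changed, the p-values of the list of Txnip neighbours on the edgeR fit were 1.344e-04 (effector) and 4.64e-06 (48 h). Its camera p-values on that fit were 0.4461 to 0.9021 and 0.1538 to 0.5702 with a library left out. Correlations were 0.714 (first transfer with WT-labelled time), 0.777 (WT-labelled with KO-labelled time), 0.043 (effector with 48 h) and 0.237 (first transfer with in vivo) with DESeq2 and 0.676, 0.702, 0.031 and 0.237 with no filter. With a library left out they were 0.851 to 0.867, 0.916 to 0.928, 0.101 to 0.165 and 0.375 to 0.397. With cycling clusters left out first transfer with WT-labelled time and with in vivo had 0.907 and 0.484. With only the groups compared, the WT-labelled with KO-labelled time and the effector with 48 h values were 0.962 and 0.342, and first transfer with in vivo was 0.323 with all barcodes and 0.346 with other cell types kept. Other cell types with all barcodes were 0% in the 4 Txnip 48 h libraries (0 in WT-labelled replicate 1, 0 in replicate 2, 0 in KO-labelled replicate 1 and 0 in replicate 2) and 2.117% in day 7 replicate 2. In the Txnip libraries this means only that no cluster of all barcodes met the rule. Among their kept cells 2, 9, 20 and 12 had been called other types, in the same order.

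The replicate numbers of the labels do not establish pairing. With the replicate block, counts were 8733, 9933, 9552, 462, 539, 182 and 9202 in the order above, and Hmox1 had 0.014 (interaction). Deviations of replicates from their group means correlated at 0.035 (first transfer), 0.229 (WT- and KO-labelled effector), 0.015 (WT-labelled effector and 48 h), -0.162 (WT-labelled effector and KO-labelled 48 h), -0.082 (KO-labelled effector and WT-labelled 48 h), -0.043 (KO-labelled effector and 48 h), 0.101 (WT- and KO-labelled 48 h) and -0.026 (in vivo).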
